A study of Rattus norvegicus with 32 samples.

How the data were processed

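Total RNA of rat nucleus accumbens was hybridised to Illumina RatRef-12 expression beadchips with 22523 probes. The deposited intensities came from BeadStudio, per the submitters' processing notes, with no version given in the sources used here. They were background-subtracted and not scaled between arrays, as their values below 0 and differing totals show. Both deposited tables held the same intensities, with a largest difference of 0. The deposited detection p-value of the first run is low for bright probes, whereas the deposited column of the same heading in the later run is a score that is high for bright probes. That score was taken as 1 minus the detection p, which the labels do not state.

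Arrays were grouped by treatment and time from the labels. The first run held METH at 1 h (5 arrays) and saline at 1 h (4). The later run held METH at 8 h (6), 16 h (6) and 24 h (5) and saline at 2 h, 4 h and 24 h (2 each), the 6 saline arrays being pooled as 1 control group. Each run was normalized by itself with neqc in limma 3.58.1 (R 4.3.3), which corrects the background from the detection p, adds an offset of 16, takes log2 and applies quantile normalization. Probes with a detection p under 0.05 on at least 4 arrays in the first run or 5 in the later run were tested, which left 9987 and 11418. Tests used lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the scale with the offset, which understates changes of dim probes. Where a gene was below background on every saline array, its fold is a bound computed against the lowest detected signal of each array or the probe's own value, whichever was higher. This bound uses group means and does not include the spread between arrays.

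Gene names came from the platform annotation, which names 1 gene for 13793 probes and none for 8730 here. No probe had several names, and 13752 probes had an Entrez ID in the RefSeq table, through which 0 names changed. One probe per gene, the brightest, stood for the gene. No build was named, so no coordinates are given. In the later run the probe IDs did not pair with the values: the rank correlation with the first run was near 0, neighbours in symbol order correlated at 0.306 in the first run and 0.0046 in the later one, and no order was recovered. One check went the other way, since pairs of probes of the same gene (492) correlated at 0.199 in the first run and 0.205 in the later one, above the highest of 1000 shufflings (0.177). The rows of the later run are therefore not named here, and the test of METH effects between runs and the pooling of all saline arrays were left out.

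Before the data were examined, 24 gene lists and the comparisons, tests, alternatives and the rule for named genes were fixed. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated one. They covered immediate early genes, MAP kinase feedback, histone acetyltransferases, deacetylases and sirtuins, repressor complexes, striatal and dopamine genes, neuropeptides, glutamate receptors, heat shock, endoplasmic reticulum stress, oxidative stress, glucocorticoid response, clock, inflammation, oxidative phosphorylation and markers of cell types and neighbouring regions. For METH against saline, the rule named the 12 largest rises and 12 largest falls among genes past the threshold that were detected on every array of a group and lay on one side of the saline mean on every METH array. It added up to 4 past-threshold members of each list with the smallest p, and Slc6a3, Th, Fos, Arc, Hdac2, Crebbp and Kat2b whatever their values. Predicted loci without a proper name were skipped. For METH against METH it allowed 5 rises and 5 falls, and it was not applied in the later run, whose probes are not named.

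Alternatives were no background correction, unscaled deposited values, no detection filter, joint normalization of all 32 arrays, no intensity trend, array weights, slide or replicate number as a block, single slides, single arrays left out, and other sets of saline arrays. No background correction means without neqc's further correction and offset, since the deposited intensities were already background-subtracted. There and in unscaled values, intensities under 16 were set to 16. Array medians in the first run were 11.9 to 18.5, so fold changes of dim genes in these 2 settings depend on that floor. The tests were checked on simulated data with 200 changed probes. Changes were added on the normalized log2 scale, and the noise was drawn independently for each probe and array. The shares called therefore leave out structure shared between probes of the real arrays. For METH at 1 h against saline, over 9987 probes, 23.9% of changes of 0.5 on the log2 scale, 85.1% of changes of 1 and 100% of changes of 2 were called. For METH at 16 h against saline, over 11418 probes, the shares were 76.1%, 100% and 100%. Camera on 7203 genes called the 1 list shifted by 0.5 and none of the others. The simulated genes were independent, whereas the correlation estimated within the lists at 1 h reached 0.53 for oxidative phosphorylation. This check therefore does not show how often camera calls lists of correlated genes by chance. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.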

Results

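Gene expression was measured in the nucleus accumbens of male Sprague-Dawley rats after a single injection of methamphetamine (METH, 20 mg/kg), a psychostimulant that releases dopamine, or of saline. The nucleus accumbens is the ventral part of the striatum. The series held 32 beadchip arrays on 4 slides. A first run of 9 arrays held 5 METH and 4 saline arrays at 1 h. A later run of 23 arrays held 6 METH arrays at 8 h, 6 at 16 h and 5 at 24 h, with 2 saline arrays each at 2 h, 4 h and 24 h. The mean intensity per array ranged from 164.3 to 231.4 in the first run and from 335.2 to 570.6 in the later run. The share of probes above background ranged from 41.5% to 47.3% and from 44.8% to 50.4%. The number of arrays limits the precision, with a median 95% interval of ±0.34 on the log2 scale at 1 h. The labels state 5 rats per group while groups held 2 to 6 arrays, so it is not known that every array came from its own rat, and the p-values measure the spread between these arrays.

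The first comparison asked which transcripts differed 1 h after METH. Most of the probes that differed rose, and 17 of them belonged to the list of immediate early genes. Of 9987 probes tested, 52 passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), of which 49 rose and 3 fell, and all 52 differed by at least 1.5-fold. Fos, a transcription factor gene switched on by neuronal activity, rose 14.3-fold (log2 fold change 3.84 ± 0.29 SE, adjusted p = 1.77e-05, n = 5 and 4). It was above background on all 5 METH arrays and on 2 of the 4 saline arrays, and its size depended on the processing, with log2 fold changes of 4.62 without background correction, 4.81 in unscaled values, 4.51 within slide 1 and 3.34 within slide 2. Arc, which encodes a synaptic protein made in active neurons, rose 7.67-fold (log2 fold change 2.94 ± 0.22 SE, adjusted p = 1.77e-05).

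Immediate early genes rose together. Of 26 measured members of this list, 17 rose over all probes tested and none fell, and 24 rose when adjusted over the list alone. The median log2 fold change of the list was 1.64 (limma's camera test, adjusted p = 7.04e-52; adjusted p = 0.00077 with an estimated correlation). Among the zinc finger transcription factors of the Egr family, Egr2 rose 6.78-fold, Egr4 6.23-fold and Egr1 3.41-fold, the last with a log2 fold change of 1.77 ± 0.10 SE. The orphan nuclear receptors Nr4a3 and Nr4a2 rose 6.40-fold and 5.09-fold. Junb, a partner of Fos in the AP-1 complex, rose 4.87-fold, Ccn1, a secreted matrix protein gene, 3.59-fold, and Ptgs2, the inducible cyclooxygenase, 3.13-fold. Gem, a small GTPase gene outside the lists, was below background on all 4 saline arrays. Its mean with METH was at least 3.59-fold that with saline, a bound that does not include the spread between arrays. Per array, the list median lay between 1.57 and 1.74 above the saline mean in the 5 METH arrays. It was 1.62 with slide as a block, 1.64 within slide 1 and 1.54 within slide 2.

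**Figure D1:**
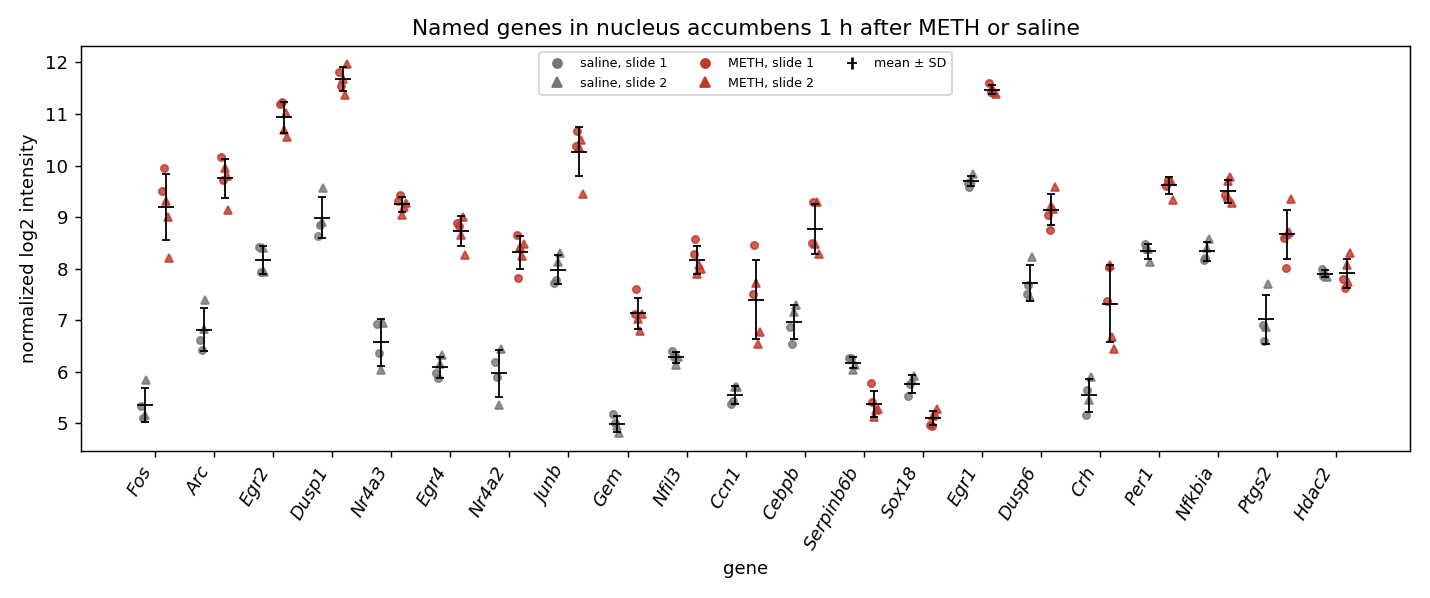
Normalized log2 intensity (vertical axis) of the 21 named genes (horizontal axis) on each array 1 h after saline (grey, n = 4) or METH (red, n = 5), with circles for slide 1, triangles for slide 2 and black bars for the mean ± SD. Fos averaged 9.20 with METH and 5.36 with saline, and Hdac2 averaged 7.91 in both groups.

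Feedback regulators of MAP kinase signalling rose as well. Of 8 measured members, 2 rose over all probes and 5 when adjusted over the list alone (camera adjusted p = 1.28e-06; adjusted p = 0.0076 with an estimated correlation). The list median was 0.58, with 0.45 within slide 1 and 0.68 within slide 2. With the median of cortical neuron markers per array as a covariate, chosen after the data were seen, it was 0.41, and 2 members rose. Dusp1, a phosphatase that inactivates MAP kinases, rose 6.44-fold (log2 fold change 2.69 ± 0.18 SE, adjusted p = 9.11e-06). Dusp6, which acts on ERK, rose 2.70-fold (log2 fold change 1.43 ± 0.19 SE, adjusted p = 0.0023).

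Genes that respond to glucocorticoids rose too, with 8 of 18 measured members up over all probes, none down, and 11 up when adjusted over the list alone. Their median log2 fold change was 0.75 (camera adjusted p = 9.29e-18; adjusted p = 0.0025 with an estimated correlation), with 0.50 within slide 1 and 0.90 within slide 2. With the cortical marker covariate 6 members rose and the median was 0.54. Per array the median was 0.42, 0.55, 0.82, 0.72 and 0.94 on METH arrays 1 to 5, where that of the cortical markers was 0.57, -0.39, 0.86, 1.48 and 1.54. Besides Dusp1, this list holds the C/EBP transcription factor gene Cebpb, which rose 3.49-fold, the clock gene Per1, which rose 2.42-fold, and Nfkbia, the inhibitor of NF-kappaB, which rose 2.24-fold. Sgk1, which rose 2.45-fold, and Tsc22d3, which rose 1.65-fold, were singled out after their values were seen. The 10 members that did not pass had log2 fold changes from -0.083 (Sult1a1) to 0.997 (Ddit4). Among them were Fkbp5 at 0.16, Mfsd2a at 0.12 and Gjb6 at 0.039. Dusp1, Per1 and Nfkbia also stand in other lists, and an action of glucocorticoids was not tested. Of 12 measured clock genes 2 rose, Per1 and Nfil3, the latter 3.69-fold, and 4 rose when adjusted over the list alone (camera adjusted p = 4.76e-05; adjusted p = 0.037 with an estimated correlation). The clock list median was 0.31, and 0.20 with the cortical marker covariate, where 2 rose. Both also stand in other lists, Per1 among the glucocorticoid-responsive genes and Nfil3 among the immediate early genes.

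Of 9 measured inflammation genes 2 rose, Ptgs2 and Nfkbia, and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.024; adjusted p = 0.116 with an estimated correlation). Ptgs2 also stands among the immediate early genes and Nfkbia among the glucocorticoid-responsive genes. Of the 32 genes written for the inflammation list, the others had no named probe or failed the detection filter. Without METH array 2 the camera adjusted p of this list was 0.056, and with the cortical marker covariate 3 members rose and 1 fell. One of 21 measured neuropeptide genes rose. This was Crh, the corticotropin-releasing hormone gene, at 3.43-fold (log2 fold change 1.78 ± 0.32 SE, adjusted p = 0.028), and it was also the 1 member that rose when adjusted over the list alone. The neuropeptide list did not pass (camera adjusted p = 0.163), but its camera adjusted p was 0.012 without METH array 5 and 0.045 without saline array 3. No heat shock gene of 16 and no endoplasmic reticulum stress gene of 21 passed over all probes, and 2 of each list rose when adjusted over the list alone. With slide as a block 2 heat shock genes and no endoplasmic reticulum stress gene passed over all probes, without METH array 5 there were 1 and 2, and in unscaled values 2 and 2. With the cortical marker covariate 5 and 2 rose, and the list medians were 0.47 and 0.21. As lists they shifted up by medians of 0.17 and 0.13 (camera adjusted p = 0.0014 and 0.00014), and with an estimated correlation the adjusted p was 0.312 and 0.096. The 2 named genes that fell were Serpinb6b, a serine protease inhibitor gene (log2 fold change -0.80 ± 0.15 SE, adjusted p = 0.027), and Sox18, an endothelial transcription factor gene (log2 fold change -0.66 ± 0.12 SE, adjusted p = 0.038). On the METH arrays Serpinb6b was above background on 3 of 5 and Sox18 on 1 of 5, so the size of either fall is uncertain. Without background correction the log2 fold changes were -1.23 and -1.12. Serpinb6b did not pass without saline array 1, 2, 3 or 4 or METH array 3 or 4 (adjusted p 0.064 to 0.106), and Sox18 without saline array 2, 3 or 4 or METH array 1, 3 or 4 (0.077 to 0.148). Among the genes that rose, Ccn1 did not pass without saline array 1, 2 or 3 or METH array 1 or 3 (0.058 to 0.092), nor Crh without any of the same arrays (0.067 to 0.123), nor Ptgs2 without saline array 2 or 3 (0.060 and 0.053).

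Genes that acetylate or deacetylate histones did not pass. None of 9 measured histone acetyltransferases, 12 deacetylases and sirtuins and 11 repressor complex genes passed over all probes or over its list alone, and camera gave adjusted p of 0.49, 0.233 and 0.959. Hdac2 had a log2 fold change of 0.0024 ± 0.15 SE (95% interval -0.32 to 0.32, adjusted p = 0.999). The dopamine transporter gene Slc6a3 was above background on 0 of 9 arrays and the tyrosine hydroxylase gene Th on 1, so neither was tested, and Crebbp and Kat2b had no named probe here. None of 14 glutamate receptor genes, 21 oxidative stress and metallothionein genes or 24 oxidative phosphorylation genes passed over all probes, with camera adjusted p of 0.423, 0.959 and 0.563. Adjusted over the list alone, 1 oxidative stress gene was higher and none of the other two lists differed. The oxidative phosphorylation median was -0.62 on METH array 5, the nearest METH array being at -0.0059.

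Markers of cortical neurons tended to be higher on METH arrays, but not on METH array 2. The 6 measured markers of cortical glutamatergic neurons had a median log2 fold change of 0.81 (camera adjusted p = 0.0095; adjusted p = 0.250 with an estimated correlation), although none passed over all probes and 2 were higher when adjusted over the list alone. The 2 were Slc17a7 and Neurod2, above background on 4 of 5 METH arrays each, but on 2 and 1 of 4 saline arrays. Saline arrays alone would not have carried either past the detection filter, so these calls and the list median lean on that filter. Of 15 markers written for this list, the others had no named probe or failed the filter. Slc17a7 had a log2 fold change of 1.80 ± 0.63 SE, of uncertain size given its detection, while Lamp5, the brightest of the 6, had -0.35 ± 0.18 SE. Per array, their median lay between -0.30 and 0.32 on the saline arrays and at 0.57, -0.39, 0.86, 1.48 and 1.54 on METH arrays 1 to 5. The 19 measured genes of striatal projection neurons and dopamine signalling had a median log2 fold change of -0.38 (camera adjusted p = 0.00013; adjusted p = 0.116 with an estimated correlation), with none past the threshold over all probes. Adjusted over the list alone, 4 were lower, namely the adenosine receptor gene Adora2a (-0.79), the signalling regulator Rgs9 (-0.57), Isl1 (-0.81) and the dopamine receptor gene Drd2 (-0.45), and Arpp21 was higher (0.63). The 15 pan-neuronal markers had a median log2 fold change of 0.29, with 1 higher when adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.196 with an estimated correlation). With slide as a block the cortical median was 0.75 and the striatal one -0.36. Within slide 1 they were 0.16 and -0.18, and within slide 2 they were 1.25 and -0.44. Markers of astrocytes (camera adjusted p = 0.233), oligodendrocytes (0.825), microglia (0.436), endothelium (0.163), choroid plexus (0.096) and neighbouring subcortical neurons (0.787) did not pass. Over the list alone, 1 choroid plexus marker was lower, and 2 markers of neighbouring neurons were higher and 1 lower. The choroid plexus list passed without METH array 2 (camera adjusted p = 0.014) and without saline array 4 (0.048), and the 3 measured blood markers were too few to test. With the cortical marker covariate the striatal median was -0.23 and the pan-neuronal one 0.092, and 63 probes passed, of which 42 were among the 52.

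**Figure D2:**
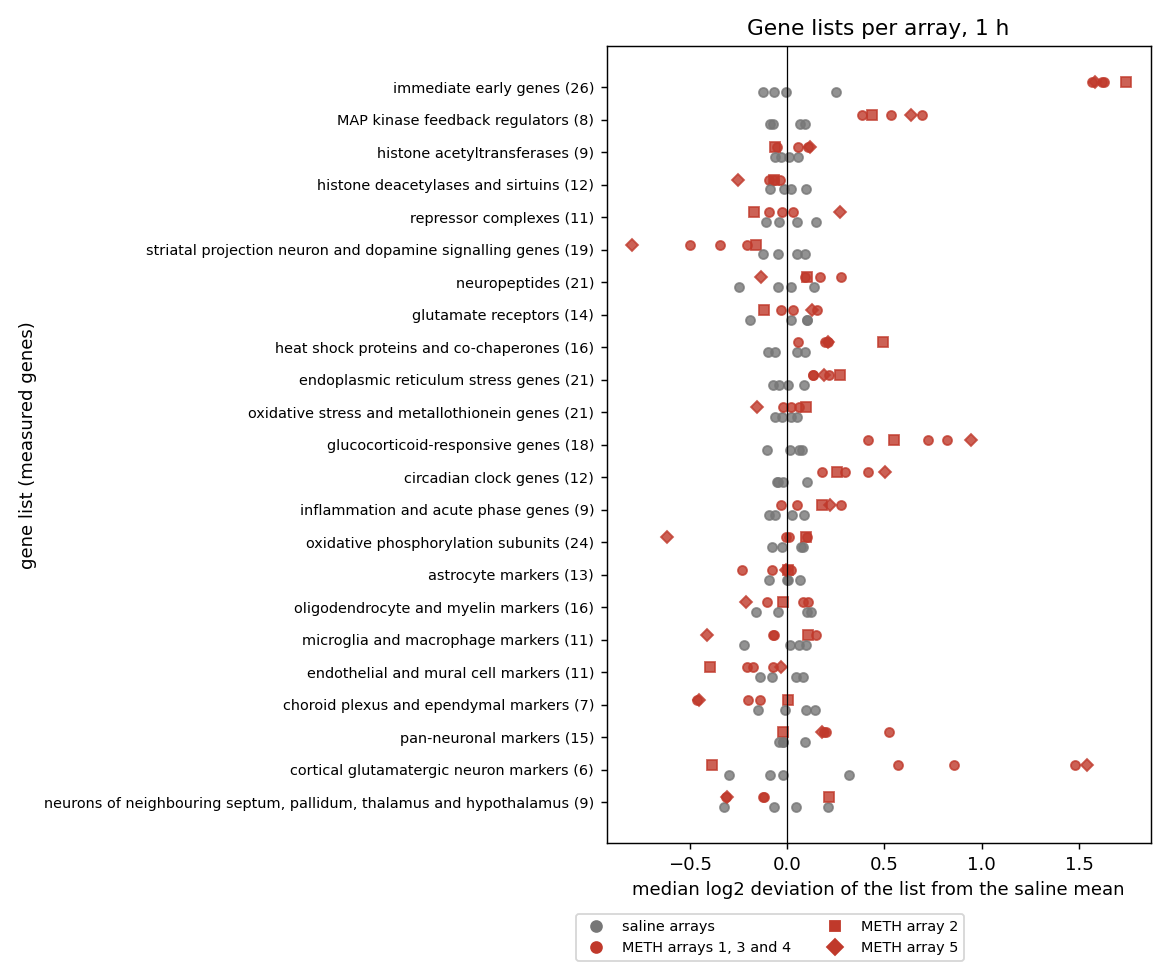
Median log2 deviation of each gene list from the saline mean (horizontal axis) on each array at 1 h, one list per row with its number of measured genes, for saline arrays (grey, n = 4) and METH arrays (red, n = 5; array 2 as a square, array 5 as a diamond). The immediate early genes lie between 1.57 and 1.74 on all 5 METH arrays, while the cortical markers range from -0.39 to 1.54.

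The count of changed probes at 1 h rested on single arrays more than the named genes did. It was 250 without METH array 2 (186 rose and 64 fell), all 52 among them, and 31 and 33 without saline arrays 2 and 3. Without METH array 5 it was 70. With slide as a block it was 62, and it was 48 within slide 1 and 16 within slide 2, where 10 of the 20 named genes, among them Junb and Per1, did not pass.

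For the later run, values could not be assigned to genes. Across all probes, the rank correlation between arrays was 0.925 to 0.961 within the first run and 0.955 to 0.976 within the later run, but -0.0095 to 0.00062 between an array of one run and an array of the other. Ribosomal protein genes of the large subunit, which are abundant in every tissue, had a median percentile of 97.4 among all probes in the first run and 48.7 in the later run. The striatal genes stood at 87.6 and 54.1. Rows stayed aligned with each other within the later run, so its comparisons are given as counts of probes with no gene names and no gene lists, and METH effects at 1 h could not be set against those at 8, 16 and 24 h gene by gene.

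**Figure D3:**
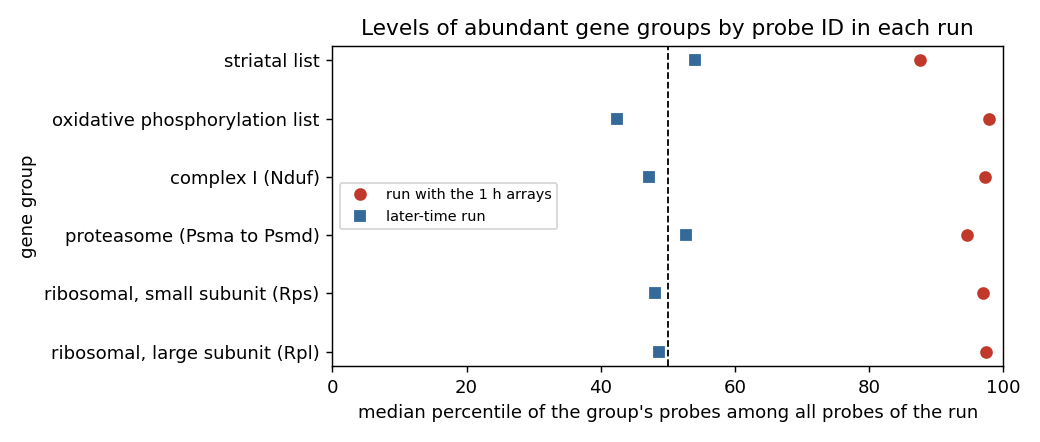
Median percentile of a gene group's probes among all probes of the run (horizontal axis, 50 marked by the dashed line) for 6 gene groups (vertical axis) in the run with the 1 h arrays (red circles) and in the later-time run (blue squares). The oxidative phosphorylation list stands at 97.8 in the first run and at 42.5 in the later one.

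The later comparisons asked which transcripts differed at 8, 16 and 24 h after METH from the pooled 6 saline arrays of the run, over 11418 probes. At 16 h, 13 probes passed, of which 11 fell and 2 rose (limma, Benjamini-Hochberg adjustment). Their median absolute log2 fold change was 0.40 and 2 of them changed by at least 1.5-fold. At 8 h no probe passed (limma, smallest adjusted p = 0.287), with 917 probes at an unadjusted p under 0.05 where chance alone gives 570.9. At 24 h no probe passed either (limma, smallest adjusted p = 0.314), with 845 at an unadjusted p under 0.05, and at 16 h there were 1256. All 13 probes had the same sign at 8 h and at 24 h, where simulated unchanged groups against the same controls gave means of 12.7 and 12.2 of 13. No saline arrays of 8 h or 16 h were analysed here, so those times were compared with saline arrays of other times.

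The 13 calls at 16 h depended on the controls and on single arrays. None passed without the saline arrays of 24 h, and 1 passed without those of 4 h. None passed without METH array 2 or METH array 3 at 16 h, or without either saline array of 24 h. Without METH array 1, METH array 5 or saline array 1 of 4 h 1 passed, without METH array 6 it was 5, without saline array 2 of 2 h 6 and without saline array 2 of 4 h 7. With slide as a block 16 passed, and within slide 3 and within slide 4 none did. For 8 h and 24 h, 0 probes passed with slide as a block. Within slide 3 none passed at either time, and within slide 4 there was 1 at 8 h and none at 24 h.

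**Figure D4:**
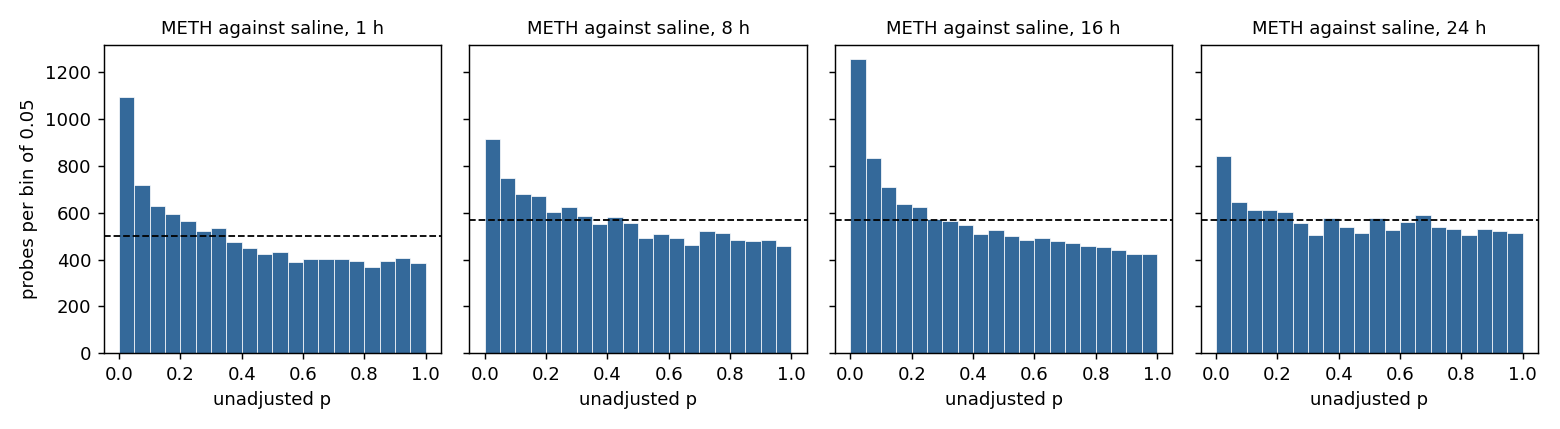
Number of probes (vertical axis) per bin of 0.05 of the unadjusted limma p (horizontal axis) for METH against saline at 1, 8, 16 and 24 h, with the number expected by chance as a dashed line (499.4 at 1 h, 570.9 at later times). The first bin holds 1097, 917, 1256 and 845 probes.

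Direct comparisons between METH times asked whether the later effects differed from each other. No probe passed between 16 h and 8 h (limma, 787 at an unadjusted p under 0.05), between 24 h and 16 h (422) or between 24 h and 8 h (663). Among the saline arrays of 2 h, 4 h and 24 h, limma's F test gave 0 probes past the threshold and 457 at an unadjusted p under 0.05. With 2 arrays per time, it cannot show that the pooled controls were alike. The saline arrays of 24 h had the highest mean intensities of the run (570.6 and 567.7). Their shares of probes above background were also the highest (49.5% and 50.4%). The saline arrays of 2 h lay on slide 3 and the others on slide 4.

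Fold changes against the shared saline arrays correlated across probes, which are not independent replicates. The correlation was 0.605 between 8 h and 16 h, 0.542 between 8 h and 24 h and 0.591 between 16 h and 24 h, where simulated unchanged groups gave 0.50, 0.471 and 0.475. The covariances were 0.0153, 0.0137 and 0.0153, against simulated ones of 0.0083, 0.0083 and 0.0082. The simulated values were independent between arrays, with no effect of slides, so an excess over them does not show shared METH effects. With the controls split into 3 and 3 arrays, the correlations were 0.102 and 0.295 for 8 h and 16 h, 0.103 and 0.190 for 8 h and 24 h, and 0.238 and 0.138 for 16 h and 24 h. With calls at 16 h alone, independent lists of calls would share 0 probes by construction, which says nothing about shared effects.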

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

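All tests of the 3 patterns weighed here were chosen after the patterns and the values per array had been seen, while slide as a block and unscaled values were planned as settings. Among the values per array, 7 stood far from the rest of their group in 106 groups of values examined, where chance gives about 5.3. Of METH array 5 at 1 h, 47.3% of probes were above background, with the nearest array at 43.5%, and its mean correlation with its run was 0.95, with the nearest at 0.969. On the same array Junb was at 9.46, the nearest at 10.4, the histone deacetylase and sirtuin list at -0.25, the nearest at -0.093, and the oxidative phosphorylation list at -0.62, the nearest at -0.0059. METH array 2 at 16 h had a mean correlation with its run of 0.981, the nearest array being at 0.986. Saline array 2 at 1 h had a pan-neuronal list median of 0.090, the nearest being at -0.021.

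The later run's values did not follow their probe IDs. Another tissue or poor RNA would leave ribosomal genes bright, and their median percentile of 48.7 argues against it. Rows in another order than the probe IDs is a candidate explanation, with neighbours in symbol order correlating at 0.0046. A random order would not give the correlation of 0.205 between probes of the same gene, so what the order is stays open. No biological explanation was tested.

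At 1 h no cortical or striatal marker passed over all probes. Neither list passed with an estimated correlation (camera adjusted p = 0.250 and 0.116). The pattern weighed was a higher cortical and a lower striatal list median in the METH group. Different amounts of cortical tissue in the dissected samples may account for it, although the test missed the mark of 0.05 set for it: within groups the 2 list medians correlated at Pearson r = -0.74 over 9 arrays (exact permutation p = 0.093, two-sided) and Spearman rho = -0.75 (exact permutation p = 0.053), each 0.093 after Benjamini-Hochberg adjustment, and at r = -0.78 and rho = -0.82 without METH arrays 4 and 5. Of the 6 markers, 3 were above background on all 4 saline arrays, and those singled out after their values were seen go both ways. Slc17a7 was above background on 2 of the 4 saline and 4 of the 5 METH arrays. It averaged 7.22 ± 1.45 (SD, n = 5) with METH and 5.41 ± 0.84 (SD, n = 4) with saline. Lamp5, the brightest, averaged 11.02 ± 0.40 and 11.38 ± 0.10. With saline the other markers averaged 5.12 to 6.35, so Lamp5 may not track cortical tissue in these samples. With slide as a block the cortical median stayed at 0.75, above the mark of 0.4 set for an effect of slides, but the blocked difference of the medians per array (0.77, SE 0.35, 95% interval -0.097 to 1.63) and the 0.16 within slide 1 leave a part of the slides open. A response of the cells to METH also stays open, with 4 of the 5 METH arrays above every saline array, so these explanations cannot be told apart.

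The rise of immediate early genes could come from cortical tissue or from the normalization. With the cortical marker median as a covariate the median of the list was 1.56, and all 17 members called before were still called, which argues against cortical tissue as the whole cause. In unscaled values the median was 2.05, where the median of all probes was 0.23 against -0.023 in the normalized values, which argues against the normalization. A response to METH is the open hypothesis for this list. The list and its camera test were fixed before the data were examined, but the rise was measured on these arrays alone.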

How the results depend on the processing

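The 20 named genes that passed at 1 h kept their direction in all 400 alternative fits and their side of the threshold in 360. Fos, Arc, Egr1, Egr2, Egr4, Nr4a2, Nr4a3, Dusp1, Gem and Nfil3 passed in all 20 alternatives, whereas Serpinb6b lost its call in 11 and Sox18 in 9. The sizes moved more: by over 1.5-fold for Fos, at 4.62 without background correction, 4.81 in unscaled values and 4.51 within slide 1, and in unscaled values for Nr4a2 (2.99), Ccn1 (2.55) and Crh (2.54). Ccn1 was also at 2.57 within slide 1 and 2.56 with the cortical covariate. The log2 fold change of Gem, 2.14 in the fit reported, was 2.90 without background correction, 3.01 in unscaled values and 2.73 with joint normalization. These values of Gem are not exact sizes, since it was below background on all 4 saline arrays. The number of arrays and signal over background limit what could be called. In unscaled values the median of all probes was 0.23 at 1 h and -0.17 at 16 h, against -0.023 and 0.0061 in the fits reported. Joint normalization kept all 52 calls at 1 h. The cause of the changes below was not tested, also where fewer arrays entered a fit.

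At 1 h, against 52 probes, 225 passed in unscaled values (224 rose), 251 with array weights (159 rose, 92 fell) and 16 within slide 2, and leaving out single arrays gave 31 to 250. At 16 h, against 13, 8 passed without background correction, 0 in unscaled values, 1 without the detection filter, 2 without the trend, 20 with array weights, 3 with the groups compared alone, 1 without saline of 4 h, 0 without saline of 24 h, 0 within slide 3 and 0 within slide 4. Leaving out single arrays gave 0 to 18. At 8 h, against 0, 4 passed without saline of 2 h and 1 within slide 4, and single arrays left out gave 0 to 2 (2 without saline array 1 of 2 h, 1 without saline array 2 of 4 h). At 24 h 1 passed against saline of 24 h alone. The average of the later times gave 5 without saline of 2 h, against 0. Saline over time gave 0 to 1 with single arrays left out (1 without saline array 1 of 4 h). Of the gene lists, 10 passed with the preset and 4 with the estimated correlation.

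With the replicate number as a block, 82 probes passed at 1 h (68 rose), 19 at 8 h and 87 at 16 h, and 0 in the other comparisons. The numbers did not pair the arrays: same-numbered METH and saline arrays at 1 h correlated at 0.072 to 0.247, and 1 of 4 correlated best with its own number. Between METH times the correlations ran from -0.15 to 0.18, and with the later saline arrays from -0.18 to 0.29 over 2 numbers.

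Hdac2, near 0, changed sign to -0.056 with array weights, -0.013 with slide as a block, -0.097 with the replicate block, -0.22 within slide 1 and -0.16 with the cortical covariate, and ran from -0.097 to 0.074 with single arrays left out. With that covariate, an alternative added after seeing the data, the list median changed sign for histone acetyltransferases (-0.024), glutamate receptors (-0.0056), oxidative stress genes (0.099), oxidative phosphorylation (0.12, camera adjusted p = 0.013) and microglia (0.12), and the neuropeptide and endothelial lists passed (camera adjusted p = 0.0018 and 0.011). With single arrays left out, medians ran from -0.031 to 0.071 for glutamate receptors, -0.018 to 0.074 for oligodendrocytes, -0.051 to 0.027 for repressor complexes, -0.065 to 0.049 for oxidative stress genes, -0.11 to 0.021 for microglia and -0.12 to 0.074 for oxidative phosphorylation. All 10 saline arrays pooled with run as a term, and the difference of effects between runs, were not run, because probe rows do not match across runs.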

Other observations

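The contrast that averages the later METH times, and its splits, were chosen after the data were seen, and the other splits were planned. Averaged over 8, 16 and 24 h, METH arrays against saline gave 0 probes past the threshold (limma, smallest adjusted p = 0.062), with 1152 at an unadjusted p under 0.05. Of 100 splits of the 23 arrays, 2 gave as many, the real one included, and the highest other gave 1284. Since the contrast was chosen after the excess at the single times was seen, these splits are no independent test of chance. Without the saline arrays of 24 h it fell to 514, under the 570.9 of chance.

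At 1 h, 4 of 100 splits of the 9 arrays, the real one included, called at least 52 probes. The highest other split called 289, so the count of 52 alone does not exclude chance. A split that calls several times the real number may reflect a structure of the samples, but what that split separates was not examined, and the split by slide called 29. The main axis of variation in the first run (first principal component) held 40.1% of the variance. On it METH array 2 (-16.1) lay with saline arrays 1 to 3 (-15.0, -17.9 and -18.8). Saline array 4 (5.0) lay with METH arrays 1, 3 and 4 (0.50, 9.7 and 11.4), and METH array 5 lay farthest out (41.1). At 16 h, 1 of 100 splits, the real one, called 13 or more, and the highest other called 2. At 8 h and 24 h and between METH times the real counts were 0, which all 100 splits reach by construction, so the splits say nothing about chance there. The highest other counts were 3 at 8 h, 1 at 24 h, 6 for 16 h against 8 h, 64 for 24 h against 16 h and 2 for 24 h against 8 h. Splits by slide called 34 probes for 24 h against saline, 1 for 16 h against 8 h, 11 for 24 h against 16 h and 0 for 24 h against 8 h, which a real count of 0 cannot be set against. With slide as a block, 0 probes passed for METH in each of these comparisons.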
